A study of Homo sapiens with 6 samples.

How the data were processed

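Messenger RNA was measured on 6 one-colour Affymetrix 3' expression arrays, 1 per transfection of MCF-7, a human luminal breast cancer cell line that expresses the estrogen receptor. Per the labels' protocols, 3 transfections received 50 nM of miR-95 and 3 received 50 nM of a scrambled control RNA, with a cationic lipid reagent, and total RNA was taken 24 h later, amplified and labelled with biotin. The sample titles gave the group and the replicate number of each array. The treatment protocol label also carries the fragment miR-9, whose meaning is unknown, and miR-95 was used because the titles and the rest of that label name it.

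The deposited table held 1 log2 value per probe set and array, made by the authors with affy and RMA per the submitters' processing notes. RMA corrects the background, forces the arrays to 1 distribution of probe intensities and summarises the probes of a probe set by median polish. The options, the chip definition, any filter and the versions are not given in the sources used here, and the table itself states neither its scale nor its centring. Base 2 was taken from RMA, and the values showed no centring of genes. The array medians were 6.74, 6.76 and 6.74 for miR-95 and 6.72, 6.74 and 6.74 for scramble. The lowest value on any array was 5.55, so dim probe sets end in a background level and their fold changes are compressed. The upper quartiles lay between 7.72 and 7.83, with all 3 miR-95 arrays below all 3 scramble arrays, so the probe set values were close to, but not at, 1 shared distribution.

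Of 54675 probe sets, 62 Affymetrix controls were set aside. By the platform annotation, 41091 of the others had 1 gene symbol, 1801 had several and 11721 had none listed. Symbols were updated through Entrez identifiers against the RefSeq gene table of GRCh38.p14, in which 41043 probe sets with 1 gene found a match and 43 changed symbol. That table was used for names only, and no coordinates are given, because the array values name no genome build. The 19752 genes with a probe set of their own were each represented by the probe set of highest mean over the 6 arrays. A floor at a mean of 5 was set in advance and removed 0 genes, since no value lay that low. ABLIM2, the gene that hosts miR-95, and miR-95 itself were not analysed here.

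The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) with no covariate and no block, and p-values were adjusted by the Benjamini-Hochberg method over all 19752 genes, with a threshold of 0.05. All fold changes are differences of group means on the log2 scale, miR-95 minus scramble, and errors given after ± are the SD over 3 arrays unless a standard error (SE) is named. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, which compares a list with all other genes, and again with a correlation estimated from the data and with fry. The 29 lists held 844 entries, of which 759 were measured, and 28 lists had at least 5 measured members and were tested. Array quality values were compared between groups with exact two-sided permutation tests, for which 3 arrays against 3 cannot give a p below 0.1. With 3 arrays per group, the number of arrays limits the precision, and p-values measure the spread between transfections of 1 cell line.

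Before the data were examined, the test, the lists, the alternatives and the rule for named genes were fixed. The rule took, among genes past the threshold whose 3 miR-95 values all lay on 1 side of the 3 scramble values, the 12 of largest decrease and the 12 of largest increase. It added the 4 reported miR-95 targets and, for each list, up to 4 members of lowest p. The alternatives were the replicate number as a block, no floor or a floor of 6, median centring, repeated quantile normalization and cyclic loess between arrays, the mean of all probe sets of a gene, any probe set of a gene, eBayes with trend and robust settings, array weights, an estimated correlation, and leaving out each array in turn. After the data were seen, a floor of 7, the 3' minus 5' difference of the ACTB control as a covariate, the removal of both arrays numbered 2, and cyclic loess together with an estimated correlation were added. The search of 3' untranslated regions for miR-95 seed sites and the ranking of 7-base words needed transcript sequences and were not run.

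The gene test was tested on simulated data with the means and spreads of the 19752 genes in this comparison. It recovered 42.6% of 68 genes changed 1.25-fold, 93.9% of 66 changed 1.5-fold and 100% of 66 changed 2-fold, and called 4 unchanged genes. The simulated genes varied independently, which real genes do not. In the same comparison a list lowered by 0.2 on the log2 scale was found at an adjusted p of 2.12e-30, and 1 of 20 runs with no shift called any list. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures with matplotlib 3.10.9.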

Results

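MicroRNAs are short RNAs that guide silencing proteins to messenger RNAs, and the comparison asked which messenger RNAs differ 24 h after MCF-7 cells receive miR-95 rather than a scrambled RNA. The data were 3 arrays of miR-95 transfections and 3 of scramble transfections, each with 54675 probe sets. Any pair of arrays correlated across probe sets at between 0.994 and 0.998, where probe sets are not independent replicates, and no pair held identical values. The closest pair, miR-95 replicates 1 and 3, differed by an SD of 0.09 on the log2 scale. Not every array was closest to its own group: miR-95 replicate 1 differed from scramble replicate 3 by an SD of 0.129 and from miR-95 replicate 2 by 0.135.

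In the deposited values, transfection of miR-95 went with decreases more often and by larger amounts than with increases. The excess in number did not hold after cyclic loess or repeated quantile normalization between arrays, while decreases of at least 1.5-fold still outnumbered such increases. The growth factor gene HDGF fell 2.52-fold, SUMF1, which encodes the enzyme that activates sulfatases, fell 2.34-fold, and ARPP19, an inhibitor of a mitotic protein phosphatase, fell 2.29-fold. The largest increase was that of DKK1, a secreted antagonist of Wnt signalling, which rose 1.64-fold. At a limma adjusted p under 0.05, 480 genes were lower and 116 were higher out of 19752, so that 80.5% of the changed genes were lower. With a fold of at least 1.5, 40 genes were lower and 2 were higher, and with a fold of at least 2, 6 were lower and 0 were higher. At an unadjusted p under 0.05 the counts were 2693 lower and 1228 higher. The median log2 fold change was -0.34 among the lower genes and 0.30 among the higher ones. In all 596 changed genes the 3 miR-95 values lay apart from the 3 scramble values, which held for 24.6% of all genes and for 10% by chance. The calls and this separation rest on the same values, so it adds no separate support to the calls.

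The split between lower and higher genes depended on the scaling: after cyclic loess between arrays 317 genes were lower and 310 higher, and after repeated quantile normalization 296 were lower and 321 higher. Of the 480 lower genes, 301 stayed past the test after cyclic loess, as did all 116 higher ones. Genes lower by at least 1.5-fold numbered 25 after cyclic loess and 24 after quantile normalization, against 5 higher genes under each. In the deposited values the median log2 fold change was 0.02 among the 4684 genes with a mean under 6.5 and -0.11 among the 2291 genes with a mean of 10 or more, and after cyclic loess these medians were 0.01 and -0.01. The counts also moved when an array was left out: 112 lower and 21 higher without scramble replicate 1, 144 and 15 without miR-95 replicate 3, 185 and 33 without miR-95 replicate 1, 277 and 75 without miR-95 replicate 2, and 725 and 115 without scramble replicate 2. The 2 genes higher by at least 1.5-fold became 1 without miR-95 replicate 1 and 5 without miR-95 replicate 2.

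**Figure D1:**
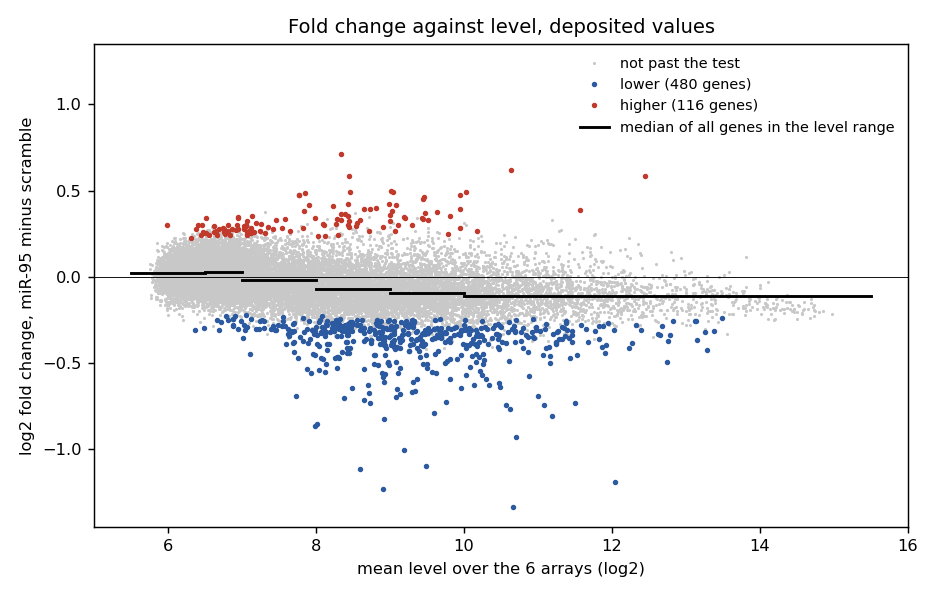
Log2 fold change (miR-95 minus scramble) of each of the 19752 genes against its mean log2 level over the 6 arrays, with genes past the test in blue (480 lower) and red (116 higher) and black lines for the median of all genes in a range of levels. The black lines lie at 0.02 at the dim end and -0.11 at the bright end, while the genes that fell most lie far below them.

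The 12 genes of largest decrease had log2 fold changes from -1.34 to -0.79. HDGF (Entrez gene 3068) stood at a log2 level of 9.99 ± 0.02 with miR-95 and 11.32 ± 0.17 with scramble (n = 3 each), a log2 fold change of -1.34 (SE 0.08, limma adjusted p = 2.97e-06). SUMF1 went from 9.52 ± 0.15 with scramble to 8.29 ± 0.08 with miR-95, and ARPP19 from 12.63 ± 0.10 to 11.44 ± 0.05. UQCC6, an assembly factor of respiratory complex III, changed by -1.12, and IMMP1L, part of the mitochondrial inner membrane peptidase, by -1.10. The membrane protein gene TMEM243 changed by -1.0, EMC8, of the endoplasmic reticulum membrane protein complex, by -0.93, and BCAT2, the mitochondrial branched-chain aminotransferase, by -0.87. DDHD2, a lipid hydrolase, changed by -0.85, the transcription elongation factor gene TCEA2 by -0.82, WDR83OS by -0.80 and SVIP, an inhibitor of endoplasmic reticulum-associated degradation, by -0.79. Of the 12 other probe sets of these genes, 11 were lower and 8 of them past the test over all probe sets. The 8 belong to ARPP19, IMMP1L, EMC8 and SVIP. HDGF, SUMF1, TMEM243, DDHD2 and WDR83OS have no other probe set, so their values rest on 1 probe set each. The exception was the dimmer probe set of BCAT2, at 0.04, and with the mean of all probe sets BCAT2 changed by -0.42, TCEA2 by -0.39 and UQCC6 by -0.67, all still past the test. The adjusted p of these 12 genes was at most 0.000625, for SVIP, and all 12 stayed past the test after cyclic loess, at log2 fold changes of -1.24 to -0.70, and without any 1 array.

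In the deposited values the 12 genes of largest increase changed less than the 12 of largest decrease. After cyclic loess their log2 fold changes were 0.52 to 0.78, which overlaps in size with the decreases. DKK1 (Entrez gene 22943) stood at 8.69 ± 0.05 with miR-95 and 7.98 ± 0.13 with scramble (n = 3 each), a log2 fold change of 0.71 (SE 0.07, limma adjusted p = 0.000413). SMIM15, which encodes a small membrane protein, changed by 0.62, the desmosomal cadherin gene DSC2 by 0.58 and XBP1, a transcription factor of the unfolded protein response and of luminal cells, by 0.58. HEATR1, which acts in ribosome biogenesis, changed by 0.50, EDN1, the precursor of the peptide endothelin, by 0.49, and the mitochondrial ribosomal protein gene MRPL50 by 0.49. LMF1, a factor for the maturation of lipases, changed by 0.49, C20orf202 by 0.48, TECPR2, which acts in autophagy, by 0.47 and MARCKS, a substrate of protein kinase C, by 0.47. UBBP1, at 0.49, is a ubiquitin pseudogene whose probes can also bind ubiquitin gene transcripts, so its identity is uncertain. The calls of UBBP1, MARCKS, C20orf202, MRPL50, SMIM15 and LMF1 were lost without at least 1 array, with highest adjusted p-values of 0.242, 0.0952, 0.0922, 0.0644, 0.06 and 0.0687, all without scramble replicate 1 except that of C20orf202, without miR-95 replicate 3. Of the 26 other probe sets of the 12 genes, 17 were higher and 1 of them past the test over all probe sets. DKK1 and SMIM15 have no other probe set. With the mean of all probe sets of a gene, XBP1 (0.23), LMF1 (0.04), C20orf202 (0.21) and MARCKS (0.12) were no longer past the test, with limma adjusted p-values of 0.0775, 0.643, 0.104 and 0.162. That mean gives dim probe sets equal weight: the other XBP1 probe set had a mean of 6.46, against 12.44 for the main one. DSC2 (0.22), HEATR1 (0.22), EDN1 (0.27), TECPR2 (0.28) and MRPL50 (0.37) stayed past the test at smaller values. UBBP1 has 1 probe set, so its 0.49 did not change, but its call was lost in that fit (limma adjusted p = 0.0888).

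**Figure D2:**
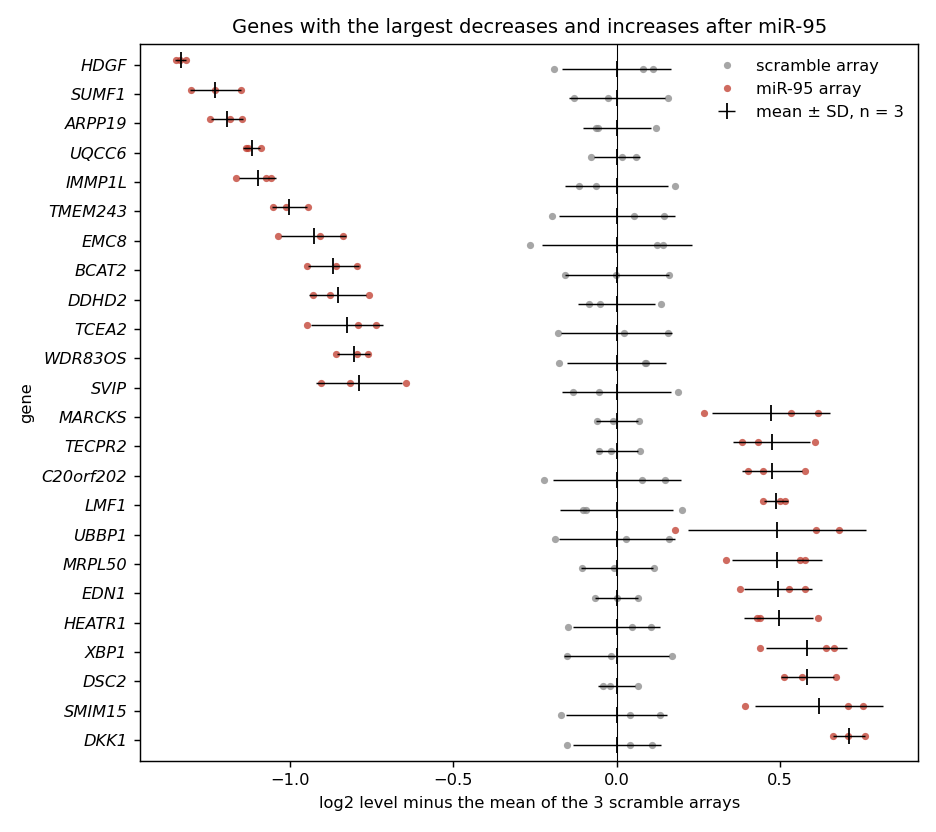
Log2 level of each array minus the mean of the 3 scramble arrays for the 12 genes of largest decrease and the 12 of largest increase, with grey points for scramble arrays, red points for miR-95 arrays and black bars for the mean ± SD (n = 3). The miR-95 means run from -1.34 for HDGF to 0.71 for DKK1. The rule for named genes took only genes whose 2 groups do not overlap, so the gap between the points was set by the selection.

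Of the 4 genes reported as miR-95 targets in earlier work, SGPP1, which encodes a sphingosine-1-phosphate phosphatase, was lower, and the other 3 were not past the test. SGPP1 (Entrez gene 81537) stood at 8.67 ± 0.21 with miR-95 and 9.05 ± 0.13 with scramble (n = 3 each), a log2 fold change of -0.39 (95% confidence interval -0.60 to -0.18, limma adjusted p = 0.0499, and 0.00599 adjusted over the list alone). Its second probe set changed by -0.33. The call sat at the threshold and was lost after cyclic loess (-0.31, adjusted p = 0.0628), and it was kept in 1 of the 6 fits that left out an array, with an adjusted p of 0.239 without scramble replicate 1. SNX1, a sorting nexin, changed by -0.02 (interval -0.24 to 0.19, adjusted p = 0.92) by its brightest probe set, and the value was 0.07 after cyclic loess. A dimmer SNX1 probe set, at a mean of 7.69, changed by -0.37 (adjusted p = 0.0478 over all probe sets), so the probe sets of this gene disagreed. CELF2, an RNA-binding protein gene, changed by 0.14 (interval 0.02 to 0.26, adjusted p = 0.2), at a level of 7.2 ± 0.03 with scramble. This gene was dim: its other probe sets had means of 5.94 to 6.37, below the array medians, where fold changes are compressed. CDKN1A, the cell cycle inhibitor p21, changed by -0.03 (interval -0.15 to 0.10, adjusted p = 0.822). Adjusted over the list alone, 1 of the 4 genes was past the test.

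Gene lists were compared with all other genes, and 11 of 28 were past the threshold by limma's camera at the preset correlation, 8 lower and 3 higher. With an estimated correlation 0 of the 28 lists were past it, and 0 had an unadjusted p under 0.05. By fry, 0 lists moved on balance in 1 direction after adjustment, 6 at an unadjusted p under 0.05, and 21 lists were past the threshold in its test for changes in either direction, which weighs all members together. The leukocyte list was among the 21 with 0 members past the test, over all genes and over the list alone. After cyclic loess 5 lists kept their call at the preset correlation, 2 lower and 3 higher. In the deposited values at that correlation, splits of the 6 arrays that mixed the groups called up to 12 lists in 1 direction, against 8 in the real split.

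Cell cycle genes were lower as a group at the preset correlation, and these lists kept their call after cyclic loess with medians of smaller size, -0.06 for G2/M and -0.07 for G1/S. With an estimated correlation neither list was past the threshold, also after cyclic loess (camera adjusted p = 0.134 and 0.136). After cyclic loess 3 and 4 of their members were past the test, and 8 and 12 members lay above 0. Of 33 measured genes of the G2/M list, 5 fell, 0 rose and 28 did not pass the test, and adjusted over the list alone 11 fell. The 5 were CENPE (-0.51), a kinetochore motor, the mitotic kinase genes AURKA (-0.47) and PLK1 (-0.28), PRC1 (-0.32), which bundles spindle microtubules, and CDC20 (-0.29), an activator of the anaphase-promoting complex. The list median was -0.15 (camera adjusted p = 6.32e-07, and adjusted p = 0.00287 after cyclic loess), with an adjusted p = 0.622 with an estimated correlation. Of 33 measured genes of G1/S and DNA replication, 5 fell, 0 rose and 28 did not pass, and 14 fell adjusted over the list alone. They were the replication factor subunits RFC3 (-0.38) and RFC4 (-0.33), the replication complex member GINS1 (-0.38), the transcription factor E2F8 (-0.36) and cyclin gene CCNE1 (-0.31). This list had a median of -0.16 (camera adjusted p = 3.66e-06, 0.00699 after cyclic loess, and adjusted p = 0.622 with an estimated correlation). GINS1 and PLK1 lay outside the rule for named genes and were added after their values were seen. After cyclic loess GINS1, PLK1 and CDC20 were not past the test, with limma adjusted p-values of 0.0887, 0.1145 and 0.077. With the mean of all probe sets of a gene, RFC3, CCNE1 and AURKA were not past it (limma adjusted p = 0.1003, 0.304 and 0.0951).

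Ribosomal proteins and oxidative phosphorylation, lists of bright genes, were lower as groups in the deposited values but not after cyclic loess. All 35 measured ribosomal protein genes had log2 fold changes below 0, with a median of -0.16 (camera adjusted p = 1.48e-07), but 0 were past the test over all genes and 3 were lower adjusted over the list alone. RPL38 had the value -0.33 (adjusted p = 0.0534) and RPS3 -0.22 (adjusted p = 0.0535). For this list the adjusted p was 0.622 with an estimated correlation and 0.145 after cyclic loess, where 7 of the members lay above 0. Of 38 oxidative phosphorylation genes, 2 fell, 0 rose and 36 did not pass, also adjusted over the list alone. ATP5F1C, a subunit of ATP synthase, changed by -0.37 and COX6A1, of cytochrome c oxidase, by -0.26. The list median was -0.15 (camera adjusted p = 3.66e-06, adjusted p = 0.622 with an estimated correlation, and 0.233 after cyclic loess).

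DICER1, which encodes the enzyme that cuts microRNA precursors, fell by 0.67 on the log2 scale by its brightest probe set (limma adjusted p = 0.000476). Some of its probe sets lay below the array medians, at means of 6.47, 6.45 and 6.29. With the mean of all its probe sets DICER1 changed by -0.22 and was not past the test (adjusted p = 0.0554), and 1 of its 5 other probe sets was past it. It was 1 of 4 genes of the list for miRNA biogenesis and silencing that fell, of 30 measured, with 0 higher and 26 not past the test, and the same 4 counted adjusted over the list alone. The others, CNOT7 (-0.34) and CNOT3 (-0.31) of the deadenylase complex and the decapping factor DCP1A (-0.28), are part of messenger RNA decay. The list median was -0.08 (camera adjusted p = 0.00953, adjusted p = 0.622 with an estimated correlation), and the call was lost after cyclic loess (adjusted p = 0.61), where the median was 0.01, and without miR-95 replicate 2 (adjusted p = 0.145). Of 34 genes of DNA double-strand break repair, 2 fell, over all genes and over the list alone: the ubiquitin ligase gene RNF8 (-0.55) and FANCI (-0.25), with a list median of -0.10 (camera adjusted p = 0.00365). This call had an adjusted p = 0.622 with an estimated correlation, 0.205 after cyclic loess and 0.0696 without miR-95 replicate 2.

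Hypoxia and glycolysis genes included 2 that fell of 35, the pyruvate kinase gene PKM (-0.40) and ANGPTL4 (-0.26), and 3 adjusted over the list alone. Their median was -0.10 (camera adjusted p = 0.00365), with an adjusted p = 0.622 with an estimated correlation and 0.656 after cyclic loess. Ribosome biogenesis and MYC target genes included 2 that fell of 29, GAR1 (-0.30) and the RNA polymerase I subunit POLR1B (-0.29), also adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.0299) with an adjusted p = 0.622 with an estimated correlation. After cyclic loess the median of that list was 0.01 and its direction turned (adjusted p = 0.998), and the adjusted p was 0.256 without miR-95 replicate 2 and 0.111 without scramble replicate 1.

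At the preset correlation, estrogen-induced genes, immediate early genes and histone genes were higher as groups, and these 3 lists kept their call after cyclic loess. With an estimated correlation they were not past the threshold, also after cyclic loess (camera adjusted p = 0.134, 0.134 and 0.301). Of 30 estrogen-induced genes, 2 rose and 1 fell, and adjusted over the list alone 7 rose and 2 fell. The scaffold gene PDZK1 changed by 0.37 and the transcription factor EGR3 by 0.28, while CCND1, which encodes cyclin D1, changed by -0.55 (limma adjusted p = 0.000625). The other CCND1 probe set changed by -0.05, and the mean of its probe sets by -0.30 (limma adjusted p = 0.0472). The list median was 0.05 (camera adjusted p = 0.00679, and 3.6e-06 after cyclic loess), with an adjusted p = 0.622 with an estimated correlation. Of 36 immediate early and MAPK feedback genes, EGR1 (0.30) and EGR3 rose and 0 fell, and 4 rose adjusted over the list alone. FOS had the value 0.29 (adjusted p = 0.0908). The median was 0.03 (camera adjusted p = 0.00953, 0.000945 after cyclic loess, and adjusted p = 0.622 with an estimated correlation), and without scramble replicate 2 the adjusted p was 0.0606. Of 13 replication-dependent histone genes, 1 rose, H2BC21 (0.34), also adjusted over the list alone. Their median was 0.06 (camera adjusted p = 0.0135, 0.0118 after cyclic loess, and adjusted p = 0.622 with an estimated correlation).

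**Figure D3:**
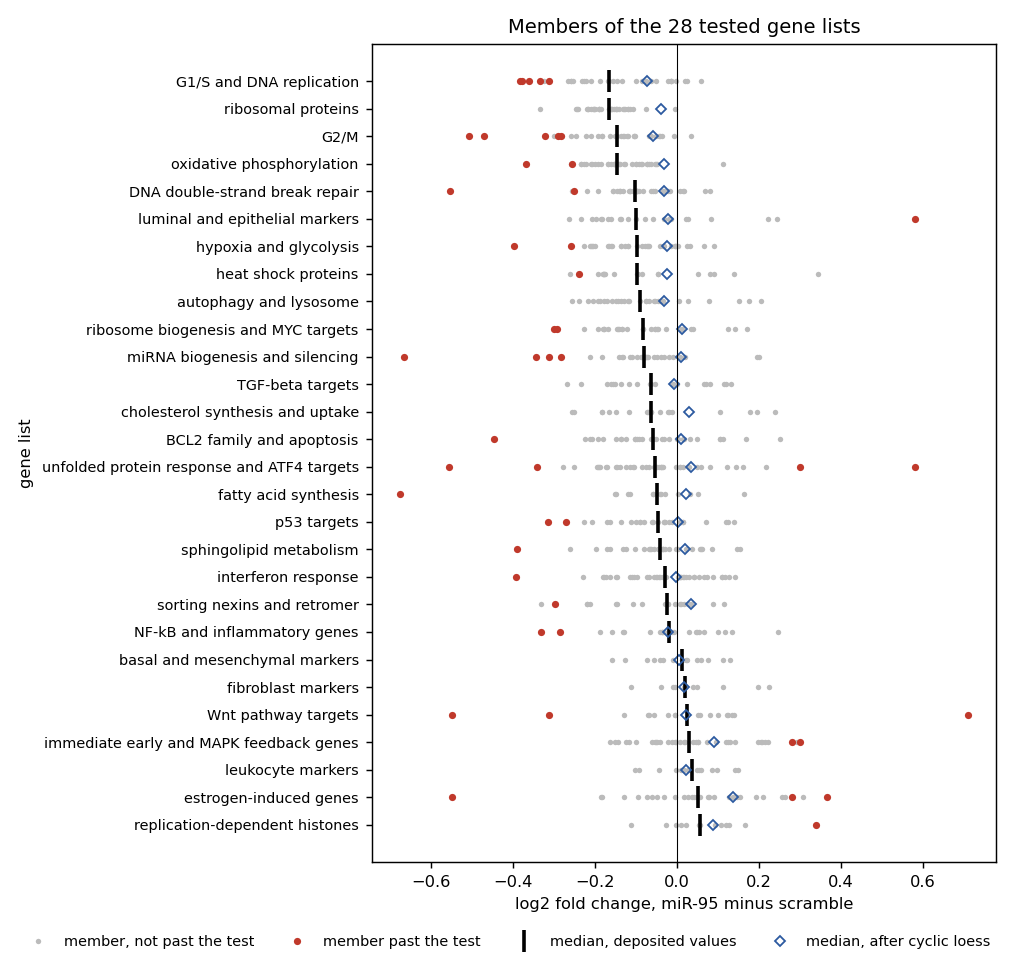
Log2 fold change (miR-95 minus scramble) of the measured members of the 28 tested gene lists, in grey where not past the test and in red where past it, with black bars for the list median in the deposited values and open blue diamonds for the median after cyclic loess. The median of ribosomal proteins moved from -0.16 to -0.04 after cyclic loess and that of estrogen-induced genes from 0.05 to 0.14.

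The other 17 lists were not past the threshold, and some held single genes that were. In the unfolded protein response and ATF4 list, XBP1 and EDEM1 (0.30) rose and SEL1L (-0.56) and HSP90B1 (-0.34) fell out of 42, and SEL1L and EDEM1 both act in endoplasmic reticulum-associated degradation (camera adjusted p = 0.229, with 3 higher and 3 lower adjusted over the list alone). The acetyl-CoA carboxylase gene ACACB was the 1 gene of 14 in fatty acid synthesis that fell (-0.68, limma adjusted p = 0.0042), and for that list the camera adjusted p was 0.255. Among 18 Wnt pathway targets DKK1 rose and CCND1 and CD44 (-0.31) fell (camera adjusted p = 0.296). CASP2 (-0.45) was the 1 gene of 33 in the BCL2 family and apoptosis list that fell (camera adjusted p = 0.228), and BST2 (-0.39) the 1 gene of 43 in the interferon response list (camera adjusted p = 0.698). The CASP2 call rests on 1 probe set: the 6 others changed by -0.12 to 0.15 with 0 past the test, and the mean of all its probe sets changed by -0.08 (limma adjusted p = 0.526). Adjusted over the list alone, these 4 lists gave 1 lower gene in fatty acid synthesis, 1 higher and 2 lower in Wnt pathway targets, 1 lower in apoptosis and 1 lower in interferon response.

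TNIP1 (-0.33) and REL (-0.29) fell out of 24 NF-kB and inflammatory genes (camera adjusted p = 0.944), and CYFIP2 (-0.31) and CCNG1 (-0.27) out of 29 p53 targets (camera adjusted p = 0.229). VPS26A (-0.30), a retromer subunit, was the 1 gene of 21 sorting nexins and retromer genes that fell (camera adjusted p = 0.157), and SGPP1 the 1 gene of 30 in sphingolipid metabolism (camera adjusted p = 0.524). HSPB1 (-0.24) was the 1 of 19 heat shock protein genes that fell (camera adjusted p = 0.128). By limma 0 genes passed among 19 of cholesterol synthesis and uptake (camera adjusted p = 0.613), 21 TGF-beta targets (0.613) and 31 of autophagy and lysosome (0.0839). Adjusted over the list alone, 1 higher and 2 lower genes passed among NF-kB genes, 2 lower among p53 targets, 4 lower among sorting nexins, 2 lower in sphingolipid metabolism, 1 higher and 4 lower among heat shock proteins, 1 higher and 1 lower in cholesterol synthesis, and 0 among TGF-beta targets and in autophagy and lysosome. Of the 41 list members named as past the test besides the 24 genes of largest change, 27 stayed past it after cyclic loess, 23 after quantile normalization and 21 with the mean of all probe sets of a gene, and 0 changed sign. The 14 lost after cyclic loess were SGPP1, CDC20, GINS1, PLK1, CNOT7, DCP1A, FANCI, COX6A1, GAR1, POLR1B, HSP90B1, CCNG1, VPS26A and HSPB1. Their log2 fold changes after cyclic loess ran from -0.31 for SGPP1 to -0.11 for HSPB1. The 20 lost with the mean of all probe sets were SGPP1, VPS26A, RFC3, CCNE1, AURKA, CYFIP2, HSP90B1, ANGPTL4, EGR1, TNIP1, REL, FANCI, CASP2, DICER1, CNOT3, CNOT7, ATP5F1C, COX6A1, POLR1B and CD44. Without scramble replicate 1, and likewise without miR-95 replicate 3, 11 of the 41 stayed past the test, 15 without miR-95 replicate 1 and 23 without miR-95 replicate 2.

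Markers of cell types were measured as a check on the makeup of the samples. XBP1 was the 1 gene of 23 luminal and epithelial markers past the test, and the estrogen receptor gene ESR1 stood at 11.63 ± 0.14 with scramble and 11.88 ± 0.06 with miR-95 (limma adjusted p = 0.0921). The camera adjusted p of the luminal list was 0.229, and adjusted over the list alone 2 of its genes were higher and 5 lower. By limma 0 of 16 basal and mesenchymal markers, 0 of 12 fibroblast markers and 0 of 14 leukocyte markers passed, with camera adjusted p-values of 0.447, 0.111 and 0.157. Adjusted over the list alone, 2 fibroblast markers were higher and 0 markers of the other 2 lists passed. The median levels of these 3 lists were 6.63, 6.53 and 6.61, close to the array medians, against 10.9 for the luminal list.

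The upper quartile of all probe sets was lower on each of the 3 miR-95 arrays (7.756, 7.723 and 7.747) than on any scramble array (7.831, 7.762 and 7.791), with means of 7.74 ± 0.02 and 7.79 ± 0.04 (exact permutation p = 0.1, the smallest that 3 arrays against 3 can give). The ACTB, GAPDH and bioB values of the groups overlapped. The 3' minus 5' difference of the ACTB control probe sets, which rises with RNA degradation and with labelling bias, was 1.62 ± 0.43 with miR-95 and 1.6 ± 0.40 with scramble (n = 3 each, exact permutation p = 1). That of GAPDH was 0.30 ± 0.13 and 0.35 ± 0.15 (exact permutation p = 0.9). The hybridization control bioB stood at 8.72 ± 0.27 with miR-95 and 9.13 ± 0.47 with scramble (exact permutation p = 0.2). The array numbered 2 had the highest ACTB difference of its group in both groups, at 2.11 and 1.95, and without both of these arrays 509 genes were lower and 100 were higher.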

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

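Cyclic loess and leaving out each array were planned as alternatives, but the tests that use them here on the share of lower genes and on the lists, the counts over splits, the correlations of same-numbered arrays, cyclic loess with an estimated correlation, the axis without its 2 farthest arrays and the count of probe sets without a single gene were chosen after the results were seen, while the relation of the within-group axis to the ACTB control was chosen before. The verdict on the cell cycle lists was first read from unadjusted p-values with an estimated correlation and was corrected, after that result was seen, to the adjusted p-values that the other lists use. The verdict on shared days or batches was first read from the lowest of 3 correlations and was left open after all 3 were weighed.

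Signal was present in probe sets that the comparison of named genes does not use. Of 13522 probe sets with no gene or several genes listed, 91 passed the limma test over all probe sets, 68 lower and 23 higher with miR-95. Of these, 58 were among the 11721 with no gene listed and 33 among the 1801 with several.

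More genes were lower than higher after miR-95. In the direction with more calls, the real grouping called 480 genes and the highest of the other splits of the 6 arrays 6, so 1 of the 10 splits called as many, and 10 splits are too few for a share under 0.05. Leaving out any 1 array never brought the share of lower genes below 78.7%, which argues against a single array as the source. For genes changed at least 1.5-fold, 83.3% were still lower after cyclic loess, which argues against unequal scaling of bright and dim probe sets as the source of the large decreases. For all called genes the share after cyclic loess was 50.6%, so unequal scaling remains a candidate explanation for the excess of small decreases. A real decrease of most bright genes would be removed by the same step and stays open and untested. Silencing of targets by miR-95 would be removed by it only as far as it moved most genes of a level, and was not tested.

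Several lists were lower as a whole after miR-95. In the direction with more lists, 4 of the 10 splits, the real one included, had at least as many past the threshold as the real one. The real split had 8 and the highest other 12. The number of lists called at the preset correlation therefore does not set the real grouping apart from mixed ones. In any case, 10 splits are too few for a share under 0.05. Of the 6 lower lists outside the cell cycle, 0 stayed past the threshold after cyclic loess, so unequal scaling of bright and dim probe sets is a candidate explanation for them. The 2 cell cycle lists both stayed past it at the preset correlation. With cyclic loess and an estimated correlation their camera p-values were 0.0143 for G2/M and 0.0194 for G1/S (adjusted 0.134 and 0.136). In the deposited values with that correlation they were 0.1475 and 0.1729. At the preset correlation cyclic loess went the other way, from adjusted p-values of 6.32e-07 and 3.66e-06 to 0.00287 and 0.00699. The estimated correlation allows for genes that vary together and does not measure scaling. For these 2 lists scaling, genes that vary together and a change in the cells therefore cannot be told apart with 3 arrays per group. A biological change in cell cycle genes after miR-95 stays open as a hypothesis.

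The arrays differed within their groups along 1 shared axis. The first principal component of the deviations from the group means held 45.6% of the within-group variance and rose with the ACTB 3' minus 5' difference (6 arrays, 1 relation computed, Pearson r = 0.954, Spearman rho = 1, both exact permutation p = 0.028 over 36 rearrangements within groups, the smallest they can give). Without the 2 arrays farthest from the median, both numbered 2, r was 0.977. A candidate explanation is RNA integrity or labelling that differed between arrays of both groups. Shared days or batches of same-numbered transfections stay open, since the same-numbered correlations of 0.030, 0.43 and 0.20 include the highest of all 9 pairs and a low one, while a pair of different numbers reached 0.32, and no biological explanation was tested.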

How the results depend on the processing

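The settings with a mean of at least 7, the ACTB covariate, arrays numbered 2 left out, and cyclic loess with an estimated correlation were chosen after seeing the data. The 24 genes of largest change kept their direction in all 456 alternative values and their call in 436. These values leave out their other probe sets, which 16 of the genes have and of which 28 of 38 had the same sign. The replicate block, the floors and the trend and robust settings do not alter a gene's fold change. Gene directions under these settings were fixed in advance, here and among all named genes. For the 24 genes, leaving out arrays and the array weights could not turn a direction either. The rule took only genes whose groups do not overlap, so these settings test the calls alone. Over all named genes, 11 of 2578 values turned and 222 lost and 147 gained a call, and over the list tests 31 of 445 turned, 36 lost and 6 gained a call. The floor of 5 removed 0 genes, so its removal tests nothing. Seed sites and 7-base words were not run. Array number and the background near 5.55 limit what dim genes can show.

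The cause was not tested for the following, except where fewer arrays or genes entered. Lower and higher genes numbered 296 and 321 with quantile normalization, 317 and 310 with cyclic loess, 287 and 69 with the mean of all probe sets, 735 and 225 with array weights and 1481 and 448 with the ACTB covariate, and 221 were higher with trend and robust settings. At 1.5-fold, lower genes numbered 24 (quantile), 25 (cyclic loess) and 19 (mean of probe sets), and higher ones 5 (quantile), 5 (cyclic loess), 4 (array weights) and 7 (arrays numbered 2 left out). Without each array in turn, lower genes ranged from 112 to 725, higher genes from 15 to 127, and at 1.5-fold from 29 to 50 and from 1 to 5. Lists past the threshold numbered 5 with cyclic loess, 7 with a mean of at least 7, 0 with an estimated correlation, 0 with cyclic loess and an estimated correlation, and 8 to 12 without each array.

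SGPP1 lost its call with median centring (-0.40), quantile (-0.31), cyclic loess (-0.31), mean of probe sets (-0.36), any probe set (-0.39), array weights (-0.30), its other probe set (-0.33) and arrays numbered 2 left out (-0.26), and ranged from -0.46 to -0.27 without each array. SNX1 turned with quantile (0.069), cyclic loess (0.066) and its dimmest probe set (0.096), passed with any probe set (-0.37), and ranged from -0.12 to 0.075 without each array. CDKN1A turned with quantile (0.083) and cyclic loess (0.075), CELF2 with 1 dimmer probe set (-0.027), COL1A1 with the mean of probe sets (-0.020), and CD79A with that mean (-0.0074) and any probe set (-0.16).

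List directions turned, with no list past the threshold on the turned side, with these unadjusted p-values. With cyclic loess they were 0.481 for sphingolipid metabolism, 0.397 for luminal markers, 0.998 for p53 targets, 0.255 for cholesterol synthesis, 0.741 for fatty acid synthesis, 0.404 for the unfolded protein response, 0.731 for TGF-beta targets, 0.914 for apoptosis, 0.995 for heat shock proteins and 0.889 for ribosome biogenesis. With an estimated correlation as well they were, in the same order, 0.605, 0.402, 0.998, 0.438, 0.846, 0.577, 0.726, 0.908, 0.995 and 0.883. With a mean of at least 7 they were 0.401 (sphingolipid metabolism), 0.901 (luminal markers), 0.451 (cholesterol synthesis), 0.943 (unfolded protein response) and 0.568 (TGF-beta targets), and with arrays numbered 2 left out 0.91 (cholesterol synthesis). Without each array the p ranged from 0.818 to 0.994 for NF-kB genes, 0.155 to 0.918 for cholesterol synthesis and 0.112 to 0.764 for sphingolipid metabolism. List tests after repeated quantile normalization are not in the count of turned list tests above. There, too, directions turned, among them sorting nexins and retromer to higher and basal and mesenchymal markers to lower (camera adjusted p = 0.984 for each).

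The replicate numbers were not taken to pair the arrays in the main fit, which was fixed before the data were examined. The deviations of same-numbered arrays correlated at 0.030, 0.43 and 0.20, and not every array correlated best with its own number. Whether the numbers pair the arrays stays open. With the replicate block 1680 genes were lower and 522 higher, with all 596 kept. The NF-kB list turned with the block (adjusted p = 0.977 by limma's camera).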

Other observations

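The comparisons in this part were chosen after the data were seen, and the genes were named after their values were seen. Probe sets of 1 gene did not always fall together. Among other probe sets with a mean of at least 7 than the brightest of their gene (7539 probe sets of 4778 genes), 449 belonged to genes that fell, and 403 of these were below 0. Their median log2 fold change was -0.17, against -0.35 for the brightest probe sets of the same genes, which were selected as past the test and so tend to the larger value. In a limma test of the difference between the probe sets of a gene, 25 of the 449 differed from the brightest one.

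TGOLN2, which encodes a protein of the trans-Golgi network, changed by -0.75 by its brightest probe set and by 0.08, 0.04 and -0.19 by 3 others that differed from it (adjusted p of the difference = 0.00858, 0.00936 and 0.0484). For UQCC6 the values were -1.12 and -0.23 (adjusted p = 0.00807), for the translation initiation factor gene EIF3B -0.73 against -0.06 and -0.04 (adjusted p = 0.00858 and 0.0295), for MCCC2, of leucine breakdown, -0.69 and 0.07 (adjusted p = 0.0136) and for the transcription factor ELK4 -0.63 against 0.0025 and -0.08 (adjusted p = 0.0136 and 0.0295). For CCND1 they were -0.55 and -0.05 (adjusted p = 0.038). Where on their transcripts these probe sets lie was not analysed here. Of 41 such probe sets of genes that rose, 25 were above 0 and 5 differed from the brightest one, among them probe sets of LMF1 and MARCKS.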
